A study of Mus musculus with 8 samples.

How the data were processed

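Gene expression was measured by strand-specific RNA sequencing of whole pancreas from 8 mice aged 6 weeks, 1 library per mouse. Per the labels' protocols, flash-frozen tissue was pulverised and homogenised in TRIzol, and libraries were prepared from total RNA with a TruSeq Stranded Total RNA kit. The labels put 4 libraries in the wild-type group and 4 in the group with floxed Daxx alleles and a Pdx1-Cre transgene, called Daxx deleted here. The series' design text gives 4 mice per genotype, 2 of each sex, so the libraries are taken as separate animals. No label says which library is from which sex. Replicates were numbered in accession order, and these numbers pair nothing across genotypes.

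The deposited table holds 1 value per gene and library, a signal that the authors made by dividing read counts by a size factor per library, as the values show. Per the submitters' processing notes, STAR 2.6.0b, DESeq2 and the genome build GRCm38 were used. The read counter, the gene filter and the version of DESeq2 are not given in the sources used here. The values of each library were whole multiples of 1 step, and dividing by it gave whole reads for 100% of values within a tolerance of 0.001. Size factors recomputed from these reads by the median of ratios equalled the inverse of the steps to within 4.44e-16. The table lists 11789 genes, and every listed gene had at least 5 reads in at least 4 libraries. Of the gene IDs, 11112 matched GENCODE M21 (GRCm38) with their version and 11781 without it. By that annotation 11778 genes are protein-coding, 3 are non-coding and 8 have no matched type. Coordinates are from this annotation.

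Library depth, as the sum of recovered reads over the listed genes, was 7705789 to 10517508. Two-way chi-square statistics of the reads of each pair of libraries of 1 genotype were 10.5 to 45.7 per degree of freedom, so no pair agreed within counting noise and all 8 libraries were kept.

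The test was fixed before the data were examined. Genes with a mean normalized count of at least 10 over all 8 libraries entered, which left 10468 genes and removed 1321. Values were taken as log2(normalized count + 1), and limma 3.58.1 (R 4.3.3) was fitted with the trend option, with genotype as the only term. P-values are two-sided with Benjamini-Hochberg adjustment, and genes under an adjusted p of 0.05 are called. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low counts. Single genes were also tested by an exact two-sided permutation test of the group means of log2 values over 70 relabellings, whose smallest possible p is 0.0286.

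The 25 gene lists, covering pancreatic cell types, other cell types of a dissection, processes linked to Daxx and the genes around the Daxx locus, were fixed before the data were examined. The 19 lists with at least 5 tested members were compared with all other tested genes by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 19 lists. The same test with an estimated correlation was an alternative. So was fry, which tests whether the genes of a list move, on balance, one way, and does not compare them with other genes. Genes are named by a rule fixed in advance: Daxx, the called genes with the largest changes, or, with fewer than 5 calls in a direction, the 5 genes with the smallest unadjusted p there, up to 3 predicted genes per direction, up to 4 members of each list with the smallest unadjusted p, hormone genes and the most abundant gene. Other genes are said to be chosen after their values were seen.

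The test was checked on simulated counts drawn with the means, size factors and dispersions of the 10468 genes, with 200 genes changed in each of 5 runs. At an adjusted p under 0.05 it called 21.2% of genes changed 1.5-fold, 78% of those changed 2-fold, 90.4% of those changed 3-fold and 94% of those changed 4-fold. Among genes with a mean of at least 100 these shares were 39.4%, 98.1%, 100% and 98.9%. Over 5 runs with no changed gene it called 3 genes in all. Over the 5 runs with changed genes it also called 53 unchanged genes. Beside these it called 53, 195, 226 and 235 of the genes changed 1.5-fold, 2-fold, 3-fold and 4-fold. A list with every member lowered to 0.7 of its level was called in 5 of 5 runs. Simulated genes varied independently, so correlated variation between animals is not part of these figures. Changing 200 genes per run also loosens the cutoff that the adjustment sets. These shares therefore do not give the power where few genes change. In runs with no changed gene a median of 511 genes had an unadjusted limma p under 0.05, against 302 in the data.

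Alternatives fixed in advance were pseudocounts of 0.5 and 8, TMM rescaling, equal library totals, quantile normalization, robust variance moderation, array weights, no filter and a minimum mean of 50, an adjusted p under 0.10, each library left out in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads. A covariate of the mean log2 level of Y-linked genes was planned with Xist, which is not among the genes analysed here, so it uses 4 Y-linked genes alone. Subtraction of each library's trend on transcript GC content (loess, span 0.3), alone and with that covariate, and a pancreatitis list without its Reg genes were added after the data were seen.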

Results

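Whole-pancreas transcriptomes were compared between 4 wild-type mice and 4 mice with floxed Daxx alleles and Pdx1-Cre, all aged 6 weeks. Daxx is a histone chaperone that, with Atrx, deposits a variant of histone H3 at silent chromatin. Pdx1-Cre recombines floxed alleles in the progenitors of acinar, ductal and endocrine cells, and leaves vessels, stroma, immune cells and fat without recombination. The comparison asks, per the series title, how basal expression in the pancreas differs without Daxx. The labels name no group with Pdx1-Cre alone or with floxed Daxx alleles alone. Effects of Daxx loss, of the transgene and of the floxed alleles therefore cannot be told apart here. The 8 libraries held 7705789 to 10517508 reads over 11789 genes. Between 74.7% and 80.3% of them fell on the 20 most abundant genes, and 27 digestive enzyme genes took 67.5% to 73.9%. Values below are the deposited normalized read counts with SD over n = 4 libraries unless stated otherwise.

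Daxx itself was lower in every Daxx-deleted library than in every wild-type library. The gene (ENSMUSG00000002307.15, chromosome 17, 33909414 to 33915590, GRCm38) had 47.6 ± 8.02 normalized counts in wild type and 28.0 ± 3.88 in Daxx-deleted pancreas, 58.8% of the wild-type mean. The log2 fold change was -0.74 ± 0.20 (SE), with a 95% interval of -1.17 to -0.31. The exact permutation test gave p = 0.0286, the smallest it can give. Over all tested genes the limma adjusted p was 0.9997, so Daxx was not among called genes. These values rest on 45 to 51 reads per wild-type library and 26 to 31 per Daxx-deleted library. Which exons the floxed allele loses is not given in the sources used here, and transcripts left after deletion, or Daxx of cells without Cre, would still give reads.

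No gene was called between the genotypes by limma with genotype as its only term, with a smallest adjusted p of 0.138. With the Y-linked level as a covariate, robust moderation or equal library totals limma called 1 gene, Bglap3. At an unadjusted p under 0.05 there were 302 genes, 138 higher and 164 lower in Daxx-deleted pancreas, where 523.4 would be expected with no change. The genes are not independent, so that figure is a loose guide. Over the other ways to split the 8 libraries into 4 and 4 the count ran from 220 to 1902. edgeR's quasi-likelihood test called 0 genes, with 299 at an unadjusted p under 0.05, and DESeq2 called 1, with 219. The median gene had an absolute log2 fold change of 0.12, and the median 95% interval reached 0.41 log2 units to each side, or 1.33-fold. The 4 values of each genotype did not overlap for 196 genes, 87 higher and 109 lower in Daxx-deleted pancreas. This is 1.87% of the genes, where chance gives 2.86%.

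DESeq2 called the same gene, Bglap3, which encodes an osteocalcin-related protein. Its mean was 9.937 ± 2.599 in wild type and 59.0 ± 33.9 in Daxx-deleted pancreas, a log2 fold change of 2.30 ± 0.36 (SE), and all 4 Daxx-deleted libraries were above all 4 wild-type libraries. Its adjusted p was 9.22e-06 in DESeq2, 0.138 in limma and 0.150 in edgeR. Over all 8 libraries limma gave 0.0146 with the Y-linked covariate, 0.0432 with robust moderation, 0.0479 with equal library totals and, in a fit chosen after seeing the data, 0.00492 with GC trend removal and the covariate. Bglap3 (ENSMUSG00000074489.9, chromosome 3, 88368616 to 88372743) has near-identical neighbouring copies, so the assignment of its reads is uncertain. Leaving out Daxx-deleted replicate 2 gave a limma adjusted p of 0.00936, and leaving out Daxx-deleted replicate 3 gave 0.920.

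The other genes with the smallest unadjusted p did not pass and are given as values. Sctr, the secretin receptor, had 7.04 ± 2.16 normalized counts in wild type and 25.6 ± 8.14 in Daxx-deleted pancreas. Naip6, of a family of inflammasome sensors with near-identical members, had 10.3 ± 8.17 and 29.8 ± 5.26. The glutamine transporter Slc38a1 had 15.9 ± 5.75 and 37.3 ± 8.51, and Axin2, a feedback regulator of Wnt signalling, had 15.7 ± 6.35 and 35.6 ± 5.47. On the other side, Igfals, which encodes the acid-labile subunit of circulating IGF complexes, had 86.04 ± 34.02 in wild type and 30.9 ± 15.4 in Daxx-deleted pancreas. The fructose transporter Slc2a5 had 19.8 ± 6.48 and 6.71 ± 3.88, and the thiamine transporter Slc19a2 had 208.6 ± 61.4 and 109.9 ± 40.2. The lectin-like receptor gene Clec2d had 137.5 ± 17.7 and 82.6 ± 17.1, and Slc35g1 had 100.4 ± 19.9 and 57.6 ± 17.7. Except for Slc19a2, the genotypes did not overlap in any of these 9 genes, and each of the other 8 had an exact permutation p of 0.0286. Since the genes were picked by their small p, this largely follows from the choice and is no further support for a difference.

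**Figure D1:**
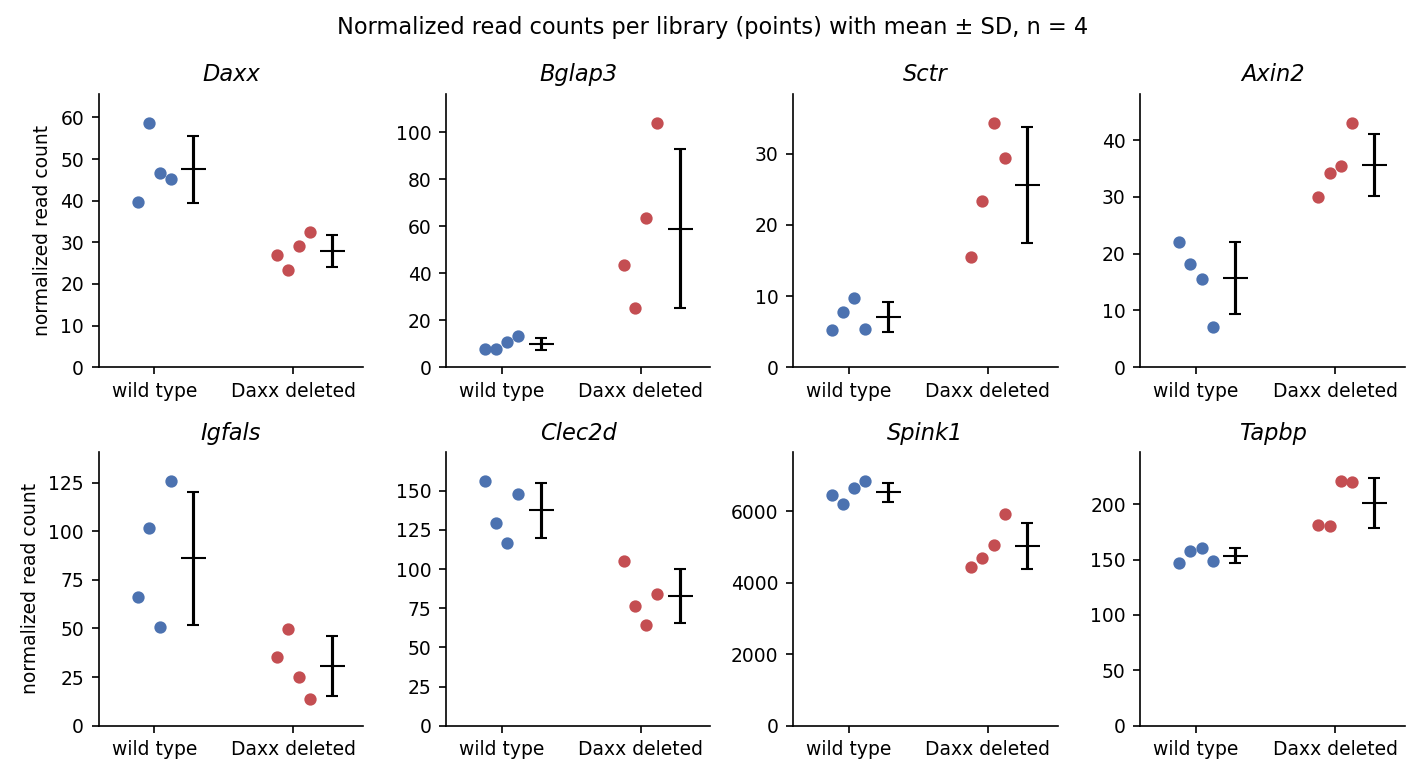
Normalized read counts (vertical axis, linear from 0) of 8 named genes in wild-type (blue) and Daxx-deleted (red) libraries, 1 point per library, with the mean and SD of the 4 libraries in black. In each of the 8 genes the 4 Daxx-deleted values lie on 1 side of the 4 wild-type values. Named genes with overlapping genotypes, such as Slc19a2, are not shown, so this separation is no further support for a difference. For Daxx the Daxx-deleted mean is 58.8% of the wild-type mean. The main limma test called none of the 8, and limma called Bglap3 in some alternative settings.

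Of the 19 gene lists tested, 1 was called. The pancreatitis acute response list, made of Reg genes, Spink1 and other genes induced in the injured pancreas, was lower in Daxx-deleted pancreas, with 10 of 12 tested members below 0 and a median log2 fold change of -0.36 (camera adjusted p = 0.0253). The list holds 26 genes, and those not tested, such as Il6, Cxcl1, Ccl2 and Lcn2, are not covered by this result. With an estimated correlation between its genes the call was lost (adjusted p = 0.859). It was also lost without wild-type replicate 1 (adjusted p = 0.127), wild-type replicate 3 (0.159) or Daxx-deleted replicate 3 (0.0706), and without the Reg genes (0.278). No member passed over all genes, and adjusted over the list alone 1 did, Spink1. This trypsin inhibitor had 6540 ± 266.8 normalized counts in wild type and 5033 ± 649.4 in Daxx-deleted pancreas, a log2 fold change of -0.39 ± 0.11 (SE). Reg3b, a C-type lectin induced by tissue injury, had 2444 ± 1987 and 1133 ± 906.0, and Reg3a had 1175 ± 1179 and 449.9 ± 462.9. Reg1 had 101843 ± 24734 and 85654 ± 19293. Within each genotype the libraries differed widely in these genes. Reg3a ran from 175.3 to 2527 in wild type and from 98.9 to 1100.4 in Daxx-deleted libraries, and Reg3b from 697.8 to 4734 and from 252.03 to 2391.

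The digestive enzymes were not called as a list (camera adjusted p = 0.0549), and none of the 27 tested enzyme genes passed, over all genes or adjusted over the list alone. The list was called lower in 8 of 23 alternative settings: with a pseudocount of 8 (adjusted p = 0.0413), TMM (0.0466), array weights (0.0271), the Y-linked covariate (0.0342), no filter (0.0377) or a minimum mean of 50 (0.0277), and without wild-type replicate 3 (0.0103) or Daxx-deleted replicate 4 (1.12e-06). With an estimated correlation the adjusted p was 0.859. Under the deposited scaling 24 of 27 had a log2 fold change below 0, with a median of -0.12, but with equal library totals 13 did and with quantile normalization 9. Quantile normalization gives every library the same set of values and so holds the most abundant genes near 0. Its count therefore cannot show whether the shift depends on scaling. Equal totals moved the median of all genes to 0.11, and relative to that median 24 of the 27 stayed below. Ctrb1, the chymotrypsinogen gene with the most reads, had 979153 ± 198583 normalized counts in wild type and 944545 ± 210475 in Daxx-deleted pancreas. The largest log2 fold change among the enzymes, -2.30 ± 0.92 (SE), was that of Ctrc, chymotrypsin C, an enzyme that degrades trypsinogen. Ctrc was at 68282, 4065, 73618 and 76266 in wild-type replicates 1 to 4 and at 57356, 2723, 3946 and 4297 in Daxx-deleted replicates 1 to 4, so that each genotype held both levels (exact permutation p = 0.0857). Its annotated span (chromosome 4, 141814962 to 141846359) overlaps that of Cela2a on the same strand. The trypsinogen gene Prss1 had 308.3 ± 158.0 and 597.3 ± 239.5, Prss3 had 9440 ± 6761 and 13691 ± 5128, and Try10 had 3777 ± 1377 and 2657 ± 328.0. In Prss1 and Prss3 every library low in Ctrc lay above every library high in Ctrc, whatever its genotype. Trypsinogen genes form a cluster of similar copies, so the split of reads between them is uncertain. Of the 18 tested genes of acinar secretion and identity, 1 passed adjusted over the list alone, again Spink1, and the list was not called (adjusted p = 0.278), but it was called lower without Daxx-deleted replicate 4 (0.00408). With an estimated correlation its adjusted p was 0.859. In this list Cuzd1, a zymogen granule membrane gene, had 21005 ± 1588 and 16905 ± 2082, Zg16 had 102838 ± 9709 and 87084 ± 9201, and the transcription factor gene Gata4 had 297.3 ± 38.2 and 340.9 ± 60.1.

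**Figure D2:**
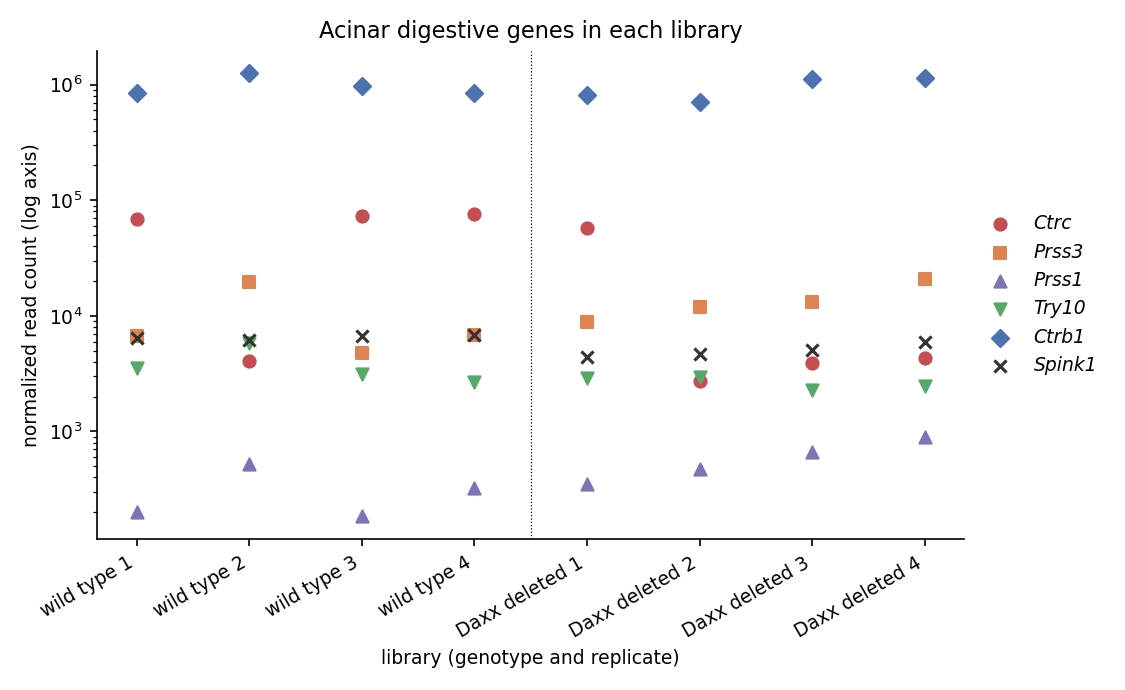
Normalized read counts (vertical axis, log scale) of 6 acinar digestive genes in each of the 8 libraries (horizontal axis, genotype and replicate), 1 marker per gene. Ctrc lies at 57356 to 76266 in 4 libraries and at 2723 to 4297 in the other 4, with both levels in each genotype, and Ctrb1 stays the most abundant of the 6 genes in every library.

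Islet and ductal genes gave no called list. Of 7 tested islet hormone genes none passed, and the list had an adjusted p of 0.278. It was called lower with equal library totals (0.0444), with array weights (0.00810), and without wild-type replicate 2 (0.0178) or Daxx-deleted replicate 3 (0.000117). Ins2 had 1861 ± 969.2 normalized counts in wild type and 1645 ± 1338 in Daxx-deleted pancreas, Ins1 had 1122 ± 596.1 and 891.0 ± 620.8, and Gcg, the glucagon gene, had 709.6 ± 487.9 and 655.8 ± 395.6. Within each genotype Ins2 varied several-fold, from 983.4 to 3201 in wild type and from 647.2 to 3517 in Daxx-deleted libraries. The 20 tested genes of islet identity and secretion had a median log2 fold change of -0.17 (adjusted p = 0.157). They were called lower with equal library totals (0.0388), array weights (0.00407) or no filter (0.0377), and without wild-type replicate 2 (0.0131), Daxx-deleted replicate 3 (6.44e-05) or Daxx-deleted replicate 4 (0.0258). With an estimated correlation both islet lists had an adjusted p of 0.859. In the identity list the prohormone convertase gene Pcsk1 had 76.3 ± 18.0 and 56.4 ± 17.3. Ductal markers had an adjusted p of 0.925 over 18 genes, with Muc1 at 782.1 ± 89.2 and 668.5 ± 93.0 and Spp1 at 249.7 ± 27.4 and 288.3 ± 25.3. Genes of acinar to ductal metaplasia had an adjusted p of 0.706 over 19 genes, with Cd44 at 26.5 ± 12.3 and 40.6 ± 18.0.

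Lists of the Daxx and Atrx pathway and of other cell processes gave no called list in the main test. RNA levels of pathway members do not measure the activity of the pathway. Over 38 genes of the Daxx and Atrx pathway and of chromatin silencing, 22 lay above 0 and 16 below (adjusted p = 0.496). The smallest unadjusted p in this list was that of Ehmt1, a histone H3 methyltransferase, with 147.6 ± 10.4 in wild type and 186.9 ± 10.5 in Daxx-deleted pancreas. Cbx5, which encodes a heterochromatin protein, had 349.0 ± 51.5 and 281.7 ± 56.5. Interferon-stimulated genes had an adjusted p of 0.278 over 17 genes, with the tetherin gene Bst2 at 51.8 ± 4.52 and 69.6 ± 15.4. The p53 targets had an adjusted p of 0.663 over 23 genes, with the kinase gene Plk2 at 401.7 ± 104.1 and 630.2 ± 141.4 and Trp53inp1 at 527.3 ± 230.7 and 326.0 ± 108.9. The unfolded protein response had 0.815 over 26 genes, with Chac1 at 273.7 ± 73.2 and 202.6 ± 62.8. Imprinted genes had 0.670 over 13 genes, with Impact at 29.5 ± 3.52 and 17.7 ± 2.57, a gene in which the genotypes did not overlap (exact permutation p = 0.0286). Impact was named for the smallest unadjusted p of its list, from which the lack of overlap partly follows. Proliferation genes had a median log2 fold change of 0.12 over 17 genes and an adjusted p of 0.0802. They were called higher with a pseudocount of 8 (0.0413), array weights (0.0271) or no filter (0.00285), and without Daxx-deleted replicate 1 (0.00661), replicate 3 (0.00801) or replicate 4 (0.00824), with an adjusted p of 0.859 with an estimated correlation. Of these, Mki67 stood at 172.4 in Daxx-deleted replicate 2 and between 50.2 and 75.6 in the other 7 libraries. Chromatin silencing keeps many germline and early embryonic genes off in somatic tissue. Of these genes, 2 of 25 in each list were tested. The germline genes were Tdrkh (25.5 ± 3.56 and 21.9 ± 4.27) and Piwil2 (19.2 ± 4.59 and 20.4 ± 3.92). The early embryonic genes were Eif1a (means 113.4 and 108.1) and Arg2 (means 49.3 and 41.2). All of them were already expressed in wild-type pancreas, so they cannot show whether silenced genes came on in Daxx-deleted pancreas.

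The genes around Daxx in the major histocompatibility region of chromosome 17 were not called as a list (31 genes, median log2 fold change 0.11, adjusted p = 0.157), and they were called higher without wild-type replicate 2 (adjusted p = 0.0439), wild-type replicate 3 (0.0444) or Daxx-deleted replicate 4 (0.00515), with an adjusted p of 0.859 with an estimated correlation. Tapbp, the tapasin gene, starts at 33915899, just after the end of Daxx, on the same strand. It had 153.6 ± 6.66 normalized counts in wild type and 200.9 ± 22.8 in Daxx-deleted pancreas, with no overlap between genotypes (exact permutation p = 0.0286) and a limma adjusted p of 0.9997. Tapbp had the smallest unadjusted p of its list, so the lack of overlap partly follows from that choice. Zbtb22, a gene outside the naming rule that was chosen after its value was seen, starts within the first part of Tapbp. It had a log2 fold change of -0.03 ± 0.14 (SE).

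Markers of other cell types gave no called list. The adjusted p was 0.933 for myeloid markers over 11 genes, 0.933 for stroma over 20, 0.663 for endothelium over 12, 0.933 for adipocytes over 10 and 0.486 for erythroid cells over 5. Adipocyte markers were called lower without Daxx-deleted replicate 2 (0.0408) and higher without Daxx-deleted replicate 4 (0.0113), with an adjusted p of 0.973 with an estimated correlation. Mrc1, of tissue macrophages, had 65.1 ± 11.8 in wild type and 71.8 ± 13.1 in Daxx-deleted pancreas, Pdgfra, of fibroblasts, had 92.7 ± 14.9 and 105.6 ± 20.1, and Kdr, of endothelium, had 155.3 ± 9.64 and 179.3 ± 32.6. Other members had lower means, among them Cd163 (32.7 ± 6.30 and 26.3 ± 13.0), Tagln (20.9 ± 8.80 and 14.6 ± 5.79), Pdgfrb (95.1 ± 15.0 and 81.9 ± 12.4) and Cdh5 (87.0 ± 14.6 and 71.3 ± 16.8). Members above and below 0 were 6 and 5 for myeloid markers, 9 and 11 for stroma and 7 and 5 for endothelium. The adipocyte gene Fabp4 stood at 124.1 in Daxx-deleted replicate 2 and between 42.5 and 62.6 in the other 7 libraries. Too few genes were tested for the list test in T cells (1 gene, Tcf7), B cells (3), gut epithelium (3) and nerve and mesothelium (4), and none of these passed. The plasma cell gene Jchain had 10.2 ± 10.2 and 24.8 ± 30.9. The median member, the mean member and the test differed in sign for metaplasia, the unfolded protein response, myeloid and stroma markers, all with medians within 0.01 of 0, and the median and mean member differed in sign for gut epithelium. No list other than the pancreatitis and acinar secretion lists had a gene that passed adjusted over the list alone.

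**Figure D3:**
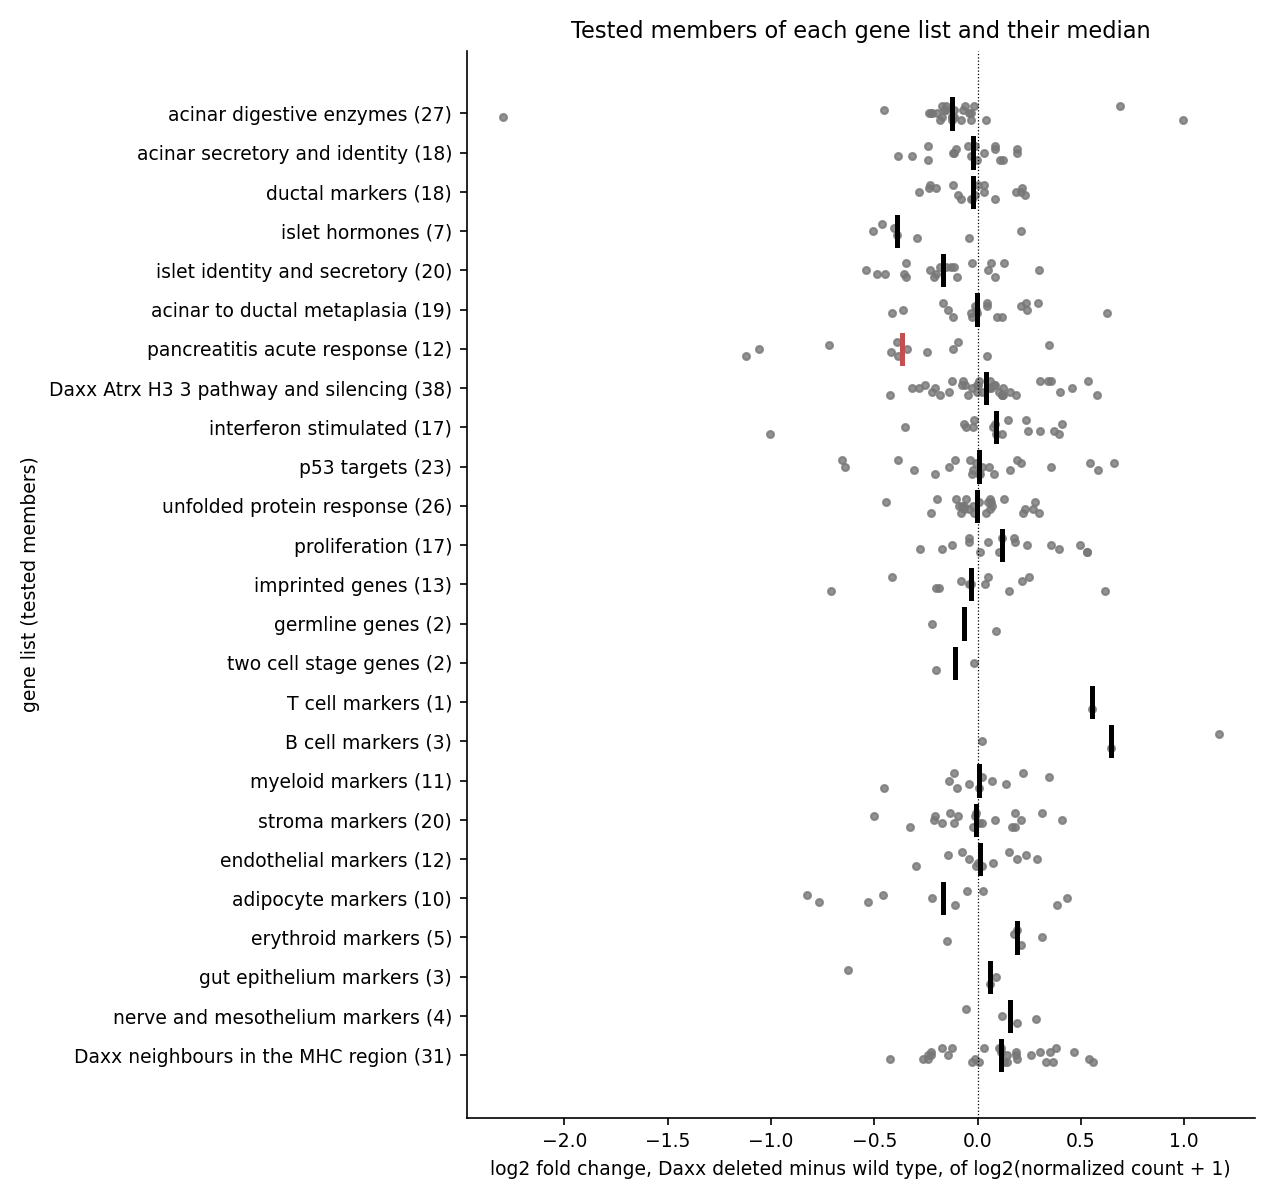
Log2 fold changes (horizontal axis, Daxx deleted minus wild type, of normalized count + 1) of the tested members of each of the 25 gene lists, 1 grey point per gene, with the number tested in brackets and the list median as a bar. The pancreatitis list, in red, is the 1 called list, with a median of -0.36; the point at -2.30 among the digestive enzymes is Ctrc.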

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

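Each group of 4 libraries was checked, for 108 named genes, for a library far from the other 3 by Dixon's test. Of 216 groups 10 had one, where chance gives 10.8. Ctrc accounts for 2 of them, with wild-type replicate 2 at 4065 against 68282 to 76266 in the other wild-type libraries, and Daxx-deleted replicate 1 at 57356 against 2723 to 4297 in the other Daxx-deleted libraries. Wild-type replicate 2 was also high in Prss3 (19488, the others 4794 to 6789) and in 1700017B05Rik (101.7, the others 68.2 to 73.1). Daxx-deleted replicate 2 was high in Mki67 (172.4, the others 57.3 to 75.6) and in Fabp4 (124.1, the others 57.3 to 58.8). Daxx-deleted replicate 3 was high in Slc2a5 (12.5, the others 4.20 to 5.16) and Daxx-deleted replicate 4 in Gata4 (430.5, the others 303.5 to 320.8). Wild-type replicate 1 was high in Peg3 (351.6, the others 250.3 to 253.0) and wild-type replicate 4 in Apoa1 (45.2, the others 2.64 to 7.83).

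The tests of Ctrc were chosen after its values were seen, and the median ratio used for the enzymes took the place of the largest ratio, which had not decided. Genotype as the whole cause is argued against by the overlap, since wild-type replicate 2 lies among the low values and Daxx-deleted replicate 1 among the high ones (exact permutation p = 0.0857). A lower share of acinar RNA in 4 libraries would lower the other abundant enzymes too, yet over the 20 other enzymes with a mean of at least 10000 the median ratio of the highest to the lowest library was 1.51, against 28.0 for Ctrc. The ratio was under 2 in 19 of them and 4.35 in Prss3, in which the highest libraries, Daxx-deleted replicate 4 and wild-type replicate 2, are low in Ctrc. A variant carried by some of the animals stays open and was not tested, C57BL/6 mice being known to carry a frameshift in Ctrc.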

How the results depend on the processing

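Daxx stayed lower, with an unadjusted p under 0.05, in each alternative in which it was tested, and leaving out 1 library at a time gave log2 fold changes of -0.82 to -0.64. The count of called genes was 0 in the other alternatives and 1, Bglap3, with equal library totals, robust moderation, the Y-linked covariate, DESeq2, and GC trend removal together with that covariate, and 0 to 1 with 1 library left out, 1 without Daxx-deleted replicate 2. Over these alternatives the adjusted p of Bglap3 ran from 9.22e-06 to 0.920, and it was not tested at a minimum mean of 50. The count of called lists was 1 in the main test, 3 with a pseudocount of 8, 2 with TMM, 3 with equal library totals, 5 with array weights, 2 with the Y-linked covariate, 4 with no filter, 2 at a minimum mean of 50, 0 with estimated correlations, 0 with fry, 0 with the Reg genes taken out of the pancreatitis list, and 0 to 7 with 1 library left out, 0 without wild-type replicate 1 and 7 without Daxx-deleted replicate 4. The adjusted p of the pancreatitis list was 0.859 with an estimated correlation, 0.986 in fry, which tests the list against no change and not against other genes, 0.278 without the Reg genes, and 0.000185 to 0.159 with 1 library left out. Adipocyte markers, below the other genes and not called, were called lower without Daxx-deleted replicate 2 (adjusted p = 0.0408) and higher without Daxx-deleted replicate 4 (0.0113), within a range of 0.0113 to 0.943 with 1 library left out, and had an adjusted p of 0.973 with an estimated correlation. Among the 18 lists other than the pancreatitis list 30 of 410 comparisons gained a call, 29 in the direction of the main test and 1, that of adipocytes, against it, and among named genes 6 of 2140, all Bglap3. The fewer libraries or genes of some settings aside, the cause was not tested. Equal library totals moved the median log2 fold change of all genes to 0.11. GC trend removal and the list without Reg genes were chosen after seeing the data. Low depth limits genes such as Daxx, at 26 to 51 reads per library.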

Other observations

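Genes in the next paragraphs were chosen after their values were seen, as were the tests of GC content on the pancreatitis list and the count of splits for called genes. The estimated correlation was among the alternatives fixed before the data were examined, but its value was known when it was taken as a test of an explanation. The search for genes at separate levels had its limits set after values had been seen, and the number of thinning draws was raised to 5 after a first draw. The other tests were set before their results were seen.

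On chromosome 6, genes in or beside the trypsinogen cluster did not differ as 1 block. Prss1 (log2 fold change 0.99), Gm10334 (1.76), Gm4744 (0.78) and 1810009J06Rik (1.15) had higher means in Daxx-deleted pancreas and Try10 (-0.45) a lower one, under the deposited scaling and with TMM, equal totals or quantile normalization, and none was called. Prss1, Gm10334 and Prss3 followed the Ctrc level. In the 4 libraries low in Ctrc they were at 473.2 to 896.6, 269.1 to 1243 and 11998 to 20875. In the 4 high in Ctrc they were at 184.0 to 348.9, 87.6 to 216.8 and 4794 to 8785. Gm4744, 1810009J06Rik and Try10 overlapped between these libraries. More of the libraries low in Ctrc were Daxx deleted than wild type, so the higher means of Prss1, Gm10334 and Prss3 cannot be assigned to genotype. The abundant members Prss2, Try4 and Try5 had log2 fold changes of -0.22, -0.18 and -0.24 under the deposited scaling, -0.10, -0.06 and -0.11 with equal totals, and 0, -0.0061 and -0.04 with quantile normalization. That normalization holds such abundant genes near 0 by its construction. Cyp26b1, a retinoic acid hydroxylase gene, was at 47.9 and 47.2 normalized counts in Daxx-deleted replicates 3 and 4 and at 0 to 8.26 in the other 6 libraries. These 2 are also the Daxx-deleted libraries with Y-linked Ddx3y above 0, and they lie on the same side of the GC split below. Sex and that side therefore cannot be told apart within the Daxx-deleted group. In wild-type replicates 3 and 4, which also had Ddx3y above 0, Cyp26b1 was at 5.84 and 0.885.

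Some genes stood at separate levels in different animals, in most of them with both levels in each genotype. A search of 7983 genes with a mean of at least 30, for a gap of at least 1.5 log2 units between libraries, with at least 2 libraries on each side and a gap of at least 4 times the sum of 0.1 and the SD within the sides, found 4 genes outside the Y chromosome, and none in 5 simulated runs. Apart from Ctrc, the ribosomal protein gene Rpl29 was at 99.3 in wild-type replicate 3 and 95.8 in Daxx-deleted replicate 2, against 297.3 to 409.5 in the other libraries. Serinc3 was at 317.0 in wild-type replicate 4 and 235.4 in Daxx-deleted replicate 3, against 1144 to 1677. Sec16b, at the lower level in Daxx-deleted libraries alone, was at 9.996 in Daxx-deleted replicate 2 and 11.5 in Daxx-deleted replicate 3, against 36.1 to 52.5. The acinar serpin gene Serpini2, which met the limits except the last, was at 557.0 in wild-type replicate 3 and 728.9 in Daxx-deleted replicate 2, against 2447 to 5940. Y-linked Ddx3y was at 0 in replicates 1 and 2 of each genotype and between 70.8 and 132.8 in replicates 3 and 4 of each.

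The 8 libraries can be split into 4 and 4 in 35 ways. The genotype split called 0 genes, which all 35 splits reach whatever the data, so this count cannot speak for or against chance; the highest other split gave 109. At least 1 list was called in 33 of 35 splits, with 13 in the highest other split and 1 in the genotype split, so chance is not excluded for the count of lists either. The preset correlation of 0.01 was below the estimate of 0.11 for the pancreatitis list and 0.85 for islet hormones.

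For the fall of the pancreatitis list, 10 of the 35 splits gave a camera p as small as the 0.00133 of the genotype split, the smallest other being 6.79e-07, so chance is not excluded. Correlated variation of its genes between animals may account for the call, since with the estimated correlation p was 0.0646. A GC trend is argued against, since p was 0.00140 after the trend was subtracted. The split of the 4 libraries high in Ctrc from the 4 low in it gave the list a camera p of 1.7e-05, below that of genotype. Spink1, the member with the smallest unadjusted p, did not overlap between genotypes, whereas each Reg gene did. An effect of genotype on Spink1 and the Reg genes stays open, and for the Reg genes it was not tested apart from the grouping by Ctrc level.

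One split points to a structure of the samples that is not genotype. Wild-type replicates 1 and 4 with Daxx-deleted replicates 1 and 2, against the other 4 libraries, gave 109 called genes, where the next highest split gave 6. The 90 genes higher in the first set had a median transcript GC content of 40.0% and the 19 lower ones 56.1%, against 49.8% over all tested genes, and across genes, which are not independent, the split's log2 fold change had a Spearman rho of -0.60 with GC content. After each library's GC trend was subtracted the split called 2 genes, consistent with a GC-dependent difference between libraries. Depth is argued against, since after thinning all libraries to 7705789 reads a median of 95 genes was called over 5 draws, between 85 and 106, and so is sex, since 192 were called with the Y-linked level as a covariate; why GC content differs between these libraries stays open. The 4 libraries of the first set had 0.166% to 0.189% of their reads on mitochondrial genes and the running numbers 1, 2, 5 and 6 in the column names, and the others 0.0769% to 0.0950% and the numbers 3, 4, 7 and 8; no label gives a batch, and none was tested. The genotype fold changes had a rho of 0.10 with GC content, and removing the GC trend left the genotype count at 0 with 409 genes at an unadjusted p under 0.05, against 302 before and 511 in the median simulated run with no change.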
